A study of Mus musculus with 9 samples.

How the data were processed

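The cerebral cortex of C57BL/6J mouse embryos at embryonic day 18.5 was profiled by RNA sequencing in 3 genotypes of the gene Cyfip2, with 3 libraries each: wild type (WT), heterozygous (Het) and homozygous mutant (KO). Groups and replicate numbers were taken from the sample labels. The labels do not say that the 3 libraries of a genotype came from separate embryos, so p-values measure the spread between these libraries. They do not describe the mutant allele. Per the labels' protocols, libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps its strand.

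The deposited table holds 1 value for each of 18820 genes in each of the 9 libraries. Its values are a signal that the authors obtained by dividing gene counts by size factors, per the file headers and the values themselves. The submitters' processing notes name Salmon 0.11.2, DESeq2 1.19.11, R 3.6.0 and the genome build GRCm38, with no role or order. How genes were chosen for the table is not given in the sources used here. Totals per library are nearly equal after this scaling, between 36.0 and 38.6 M (M, mega), and the median ratio to the geometric mean over libraries is 1.00 in each of the 9. In each library, low values cluster around multiples of a step worth about 1 read, from 0.675 in WT replicate 2 to 1.22 in KO replicate 1. Dividing the totals by these steps gives an approximate depth of 29.5 M reads (KO replicate 1) to 54.4 M (WT replicate 2). Between 60.8% and 78.2% of the values below 6 lay within 0.1 of a whole number of steps. Reads could not be recovered as whole numbers, so tests that need counts were not used.

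The test planned first was a count test with a stated fallback for values already divided by size factors, and the fallback was used. Values were taken as log2(value + 1), with no further scaling, for the 15069 genes with a mean of at least 10 over the 9 libraries. Fold changes on this scale understate the change of low genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per genotype over all 9 libraries (lmFit, then eBayes with a trend), so that the genotypes shared 1 estimate of the spread. 4 contrasts were tested, two-sided: KO against WT, Het against WT, KO against Het, and Het against the midpoint of WT and KO on the log2 scale. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Errors beside group means are SDs over 3 libraries, and errors beside log2 fold changes are limma standard errors (SE). For Cyfip2 and Fndc9, exact permutation tests compared 3 libraries with 3, for which the smallest possible two-sided p is 0.10.

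36 gene lists were fixed before the data were examined, and 35 with at least 5 tested members were tested with camera (limma, preset inter-gene correlation of 0.01), adjusted over the lists within a contrast. The sex-linked list had 4 tested members and was not tested. Camera was repeated with an estimated correlation, and fry (limma) was run on the same lists. The pathway lists covered the WAVE regulatory complex, actin regulators, FMRP and translation partners, collagens, basement membrane, matrix glycoproteins, matrix crosslinking, synapse, axon guidance, immediate early genes, cell cycle, p53 and apoptosis, hypoxia and glycolysis, unfolded protein and heat shock response, oxidative phosphorylation, cytosolic ribosomal proteins, growth hormone and IGF signalling, and genes near Cyfip2. The other lists were markers of cell types and tissues that cortical dissections can hold. The matrix lists were chosen knowing that the published study of these mice discussed matrix genes.

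The rule for named genes was fixed in advance. It takes Cyfip2, the tested members of the WAVE complex list, genes past the threshold ranked by fold change, or, where fewer than 3 passed in a direction, the 3 with the smallest p given as not passing, and up to 4 members with the smallest p from each called list. Gene models without a proper name were counted but not named. To keep the text short, a choice made after the values were seen, the KO against Het and Het against midpoint comparisons name 1 member per called list, the one with the smallest p, and the WAVE members are given for KO against WT. The results of 2 genes that the rule takes are not reported here. The stability of all 242 gene results that the full rule takes is counted in the closing section. Fndc9 was singled out after its values were seen, and also falls under the rule.

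Symbols and coordinates came from GENCODE release M21 (GRCm38); 18783 of the 18820 gene IDs matched a symbol. The sex of each library was read from 4 Y-linked genes after the data were seen. Scores for olfactory bulb and meningeal tissue are medians of log2 values, centred over the libraries, of 10 and 17 marker genes.

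Alternatives fixed in advance were the replicate number as a block, pseudocounts of 0.5 and 5, other filters on low values, quantile and upper-quartile rescaling, a fit to the compared groups alone, and leaving out each library in turn. Residuals of libraries with the same replicate number correlated at 0.45, 0.10 and 0.47 between Het and KO, but at -0.07 to 0.25 between WT and the others, and 4 of 6 Het and KO pairs of different numbers were negative. The labels do not say what a number marks. Het replicate 2 with KO replicate 1 (0.15) and Het replicate 1 with KO replicate 2 (0.12) lay above the same-number pair at 0.10. For 2 of 9 libraries the own number correlated best within both other genotypes. Het replicate 1 and KO replicate 1, Het replicate 3 and KO replicate 3, and WT replicate 2 and Het replicate 2 were each other's closest partners. Residuals are centred within each genotype, so positive same-number pairs bring negative ones elsewhere. Het replicate 1 and KO replicate 1 were both female with olfactory bulb RNA, and Het replicate 3 and KO replicate 3 both male with little of it. The correlations cannot tell pairing from these shared traits. The block is thus given beside a result for KO against Het where it changes a call. Those added after seeing the data were a fit to the Het and KO libraries alone with the replicate block, sex, the olfactory bulb score or the meningeal score as a covariate, array weights, and leaving out Het replicate 3 and KO replicate 3 together. The gene test was checked on simulated data of the same 15069 genes, each given its own measured spread. For KO against WT it recovered 40% of genes changed by 0.5 on the log2 scale, 66% of those changed by 1 and 88% of those changed by 2, with 6 wrong calls. The real data are harder than that simulation, which drew genes independently of each other. It also changed 50 genes at each of log2 0.5, 1, 2 and 3 together, which loosens the Benjamini and Hochberg cutoff. The shares recovered are thus too high for data with few changed genes.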

Results

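RNA was sequenced from the cortex of mouse embryos at embryonic day 18.5, in 3 wild-type, 3 heterozygous and 3 homozygous mutant libraries for Cyfip2. Cyfip2 encodes a subunit of the WAVE regulatory complex, which controls the assembly of branched actin. Approximate depth ran from 29.5 M reads (M, mega) in KO replicate 1 to 54.4 M in WT replicate 2, and 15069 genes were tested.

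Cyfip2 (ENSMUSG00000020340) was measured first in every library, since it checks the labels. Its normalized counts were 10169, 10345 and 11174 in the WT libraries, 8969, 9779 and 9882 in the Het libraries, and 7900, 7522 and 8255 in the KO libraries. The groups did not overlap, and their means were 10562 ± 537, 9543 ± 500 and 7893 ± 366 (SD, n = 3 each). Cyfip2 RNA in KO was 74.7% of its WT level, a log2 fold change of -0.42 ± 0.06 (SE), with a 95% interval from -0.56 to -0.28. The gene lies on the minus strand of chromosome 11 from 46193850 to 46312859 (GRCm38), and the deposited value covers the whole gene, so it cannot show whether a deleted part was missing from this RNA.

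Fndc9 (ENSMUSG00000048721), which encodes a fibronectin type III domain protein, lies at 46235531 to 46239872 on the plus strand of the same chromosome. The annotation places it inside an intron of Cyfip2, between exons that end at 46224205 and start at 46240004. Its normalized counts were 42.7 ± 19.1 in WT, 21.1 ± 5.54 in Het and 2.63 ± 1.80 in KO (SD, n = 3 each), and the KO to WT log2 fold change was -3.64 ± 0.48 (SE), with a 95% interval from -4.72 to -2.55. The KO values of Fndc9, 0.914 to 4.50, lie near the floor, since 1 read is worth 0.92 to 1.22 in these libraries. Its log2 fold change was -3.88 with a pseudocount of 0.5 and -2.60 with 5, a choice the interval does not cover. Both Cyfip2 and Fndc9 ranked all 3 WT libraries above all 3 Het libraries and these above all 3 KO libraries. The exact permutation p for each pair of groups was 0.10, the smallest possible with 3 against 3.

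**Figure D1:**
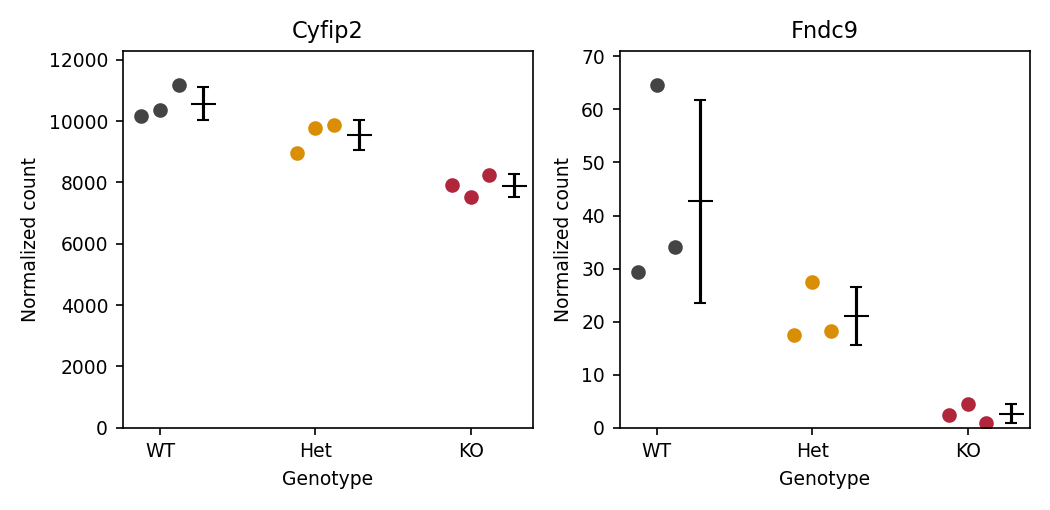
Normalized counts (vertical axis, from 0) of Cyfip2 and Fndc9 by genotype, with 1 point per library and the mean ± SD of 3 libraries beside it. The KO libraries lie at 7522 to 8255 for Cyfip2 and at 0.914 to 4.50 for Fndc9, below all Het and WT libraries.

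Marker genes showed that the libraries differed in tissue and sex in ways the genotype labels do not give. Cdhr1, a marker of olfactory bulb mitral cells, was at 2230 in WT replicate 3, 3436 in Het replicate 1, 3237 in KO replicate 1 and 2138 in KO replicate 2, and between 21.8 and 53.1 in the other libraries. Ttr, made by choroid plexus, reached 3156 in WT replicate 2 and 11029 in Het replicate 2. The globin gene Hbb-bs ran from 8460 in KO replicate 2 to 30474 in KO replicate 1. Het replicate 3 was low in meningeal genes, with Col1a1 at 87.2 against 2206 to 5328 in the other 8 libraries and Dcn at 23.9 against 898 to 2227. Ddx3y, a Y-linked gene, was listed at 0 in Het replicate 1, KO replicate 1 and KO replicate 2 and lay between 1394 and 1674 in the other libraries. By the Y-linked genes all 3 WT libraries were male, as were 2 of 3 Het libraries and 1 of 3 KO libraries.

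**Figure D2:**
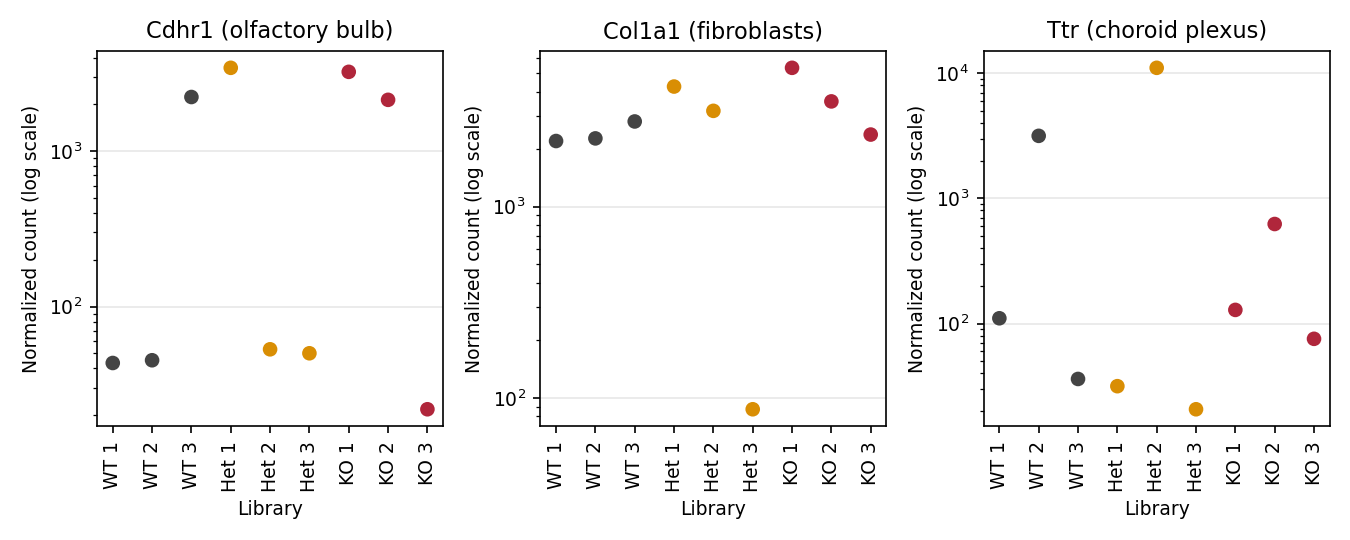
Normalized counts (logarithmic vertical axis) of Cdhr1, Col1a1 and Ttr in each of the 9 libraries, coloured by genotype. Cdhr1 is above 2000 in 4 libraries, Col1a1 is at 87.2 in Het replicate 3, and Ttr is at 11029 in Het replicate 2.

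The comparison of KO with WT asked what changes when both copies of Cyfip2 are mutant. Cyfip2 was the only member of the WAVE complex that differed: it was called lower when adjusted over the list alone (adjusted p = 0.00099) but not over all genes tested (adjusted p = 0.678). Its paralog Cyfip1, the alternative subunit of the same complex, was at 3827 ± 133 in WT and 3894 ± 172 in KO (SD, n = 3), a log2 fold change of 0.02 ± 0.05. Genes of basement membrane had a positive median log2 fold change in KO, with the laminin chain Lamc1 at 3379 ± 41.5 in WT and 5212 ± 1138 in KO, but no member passed, and the list had an adjusted p = 0.772 with an estimated correlation and was not called without KO replicate 1 or with sex as a covariate. Genes of mitochondrial respiration and the ribosome had small negative values in nearly every member of their lists, with no member passing and an adjusted p = 0.749 with an estimated correlation for both.

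In the WAVE complex list, 1 of 11 members passed adjusted over the list alone, and 0 passed over all genes. The scaffold subunit Nckap1 had a log2 fold change of -0.09 ± 0.08 and its blood-cell relative Nckap1l 0.16 ± 0.27. The values were -0.03 ± 0.10 for Wasf1, 0.03 ± 0.25 for Wasf2 and -0.06 ± 0.09 for Wasf3, which encode the actin-activating subunits. They were 0.10 ± 0.05 for Abi1, 0.07 ± 0.10 for Abi2, 0.38 ± 0.43 for Abi3 and 0.02 ± 0.06 for Brk1. The list as a whole was not called by camera (adjusted p = 0.75).

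Over all genes, limma called 0 higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.589. At an unadjusted p under 0.05 there were 82 higher and 96 lower, 178 in all where 753 would be expected by chance. A single grouping can lie far from that figure: the 10 splits of these 6 libraries gave 123 to 1357 such genes. The KO and WT libraries did not overlap for 6.46% of genes, where chance gives 10%. The genes with the smallest p, none passing, were Fndc9, Cyfip2 and Mrps23 among the lower ones. Mrps23, a mitochondrial ribosome protein, was at 1403 ± 61.1 in WT and 1037 ± 144 in KO (log2 -0.44 ± 0.10). Among the higher ones they were the lipoxygenase Aloxe3, at 69.4 ± 2.45 in WT and 152 ± 37.7 in KO (log2 1.09 ± 0.22), Dpm1, a subunit of the enzyme that makes dolichol phosphate mannose (0.42 ± 0.11), and the small GTPase Arl4a (0.23 ± 0.07).

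10 of 35 gene lists were called by camera with the preset correlation, 7 higher and 3 lower in KO, and 0 with an estimated correlation or with fry. In no called list did any member pass over all genes, and adjusted over the list alone a member passed in only 1 of them, Fndc9. The matrix lists were chosen knowing that the published study discussed such genes, so they are not independent evidence. 20 of 21 basement membrane genes were higher (median log2 0.38, adjusted p = 2.49e-05, and adjusted p = 0.772 with an estimated correlation). Besides Lamc1, these were Col4a2 (0.47 ± 0.34), which makes collagen IV, and the laminin chains Lama4 (0.41 ± 0.33) and Lama2 (0.38 ± 0.32). All 24 collagens were higher (median 0.42, adjusted p = 0.00166, and adjusted p = 0.792 with an estimated correlation), with Col11a2 at 0.44 ± 0.27, Col25a1 at 0.69 ± 0.56, Col23a1 at 0.31 ± 0.26 and Col11a1 at 0.18 ± 0.16. Of the matrix glycoproteins and proteoglycans, 30 of 35 were higher (median 0.22, adjusted p = 0.00178, and adjusted p = 0.772 with an estimated correlation). The proteoglycan Vcan had a log2 fold change of 0.22 ± 0.08, the microfibril protein Fbn1 0.27 ± 0.12, Igfbp7 0.31 ± 0.19 and Tgfbi 0.62 ± 0.44.

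Markers of vessel cells went the same way. All 15 pericyte and smooth muscle markers were higher (median 0.33, adjusted p = 0.000344, and adjusted p = 0.772 with an estimated correlation), with the muscle filament gene Des at 0.70 ± 0.43, Higd1b at 0.32 ± 0.21, Cspg4 at 0.16 ± 0.11 and Abcc9 at 0.19 ± 0.14. 16 of 18 endothelial markers were higher (median 0.28, adjusted p = 0.00166, and adjusted p = 0.792 with an estimated correlation), with the VEGF receptor Flt1 at 0.43 ± 0.21, Pecam1 at 0.41 ± 0.24, Robo4 at 0.36 ± 0.23 and the glucose transporter Slc2a1 at 0.32 ± 0.20. The medians over the genes of the 6 matrix and vascular lists, relative to the WT mean, were 0.60, 0.24 and 0.03 in KO replicates 1, 2 and 3. They were at most 0.07 in WT, and 0.34, 0.14 and -0.76 in Het replicates 1, 2 and 3. Het replicates 1 and 2 thus also lay above all WT libraries. Without KO replicate 1, 0 of these 5 called lists were called, and with sex as a covariate 0 were called.

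Striatal projection neuron markers were higher for 15 of 16 members (median 0.59, adjusted p = 0.000858, and adjusted p = 0.749 with an estimated correlation). They included the transcription factor Foxp1 (0.32 ± 0.14), the adenosine receptor Adora2a (0.63 ± 0.42) and the enkephalin gene Penk (0.40 ± 0.35). The list's median stood at 1.00 and 1.29 in KO replicates 1 and 2, at 1.07 in Het replicate 1 and at -0.45 in KO replicate 3. The first 3 of these libraries are the females, and they also carried olfactory bulb RNA; with sex as a covariate the list median was -0.39. Of the hypoxia and glycolysis genes, 19 of 21 were higher (median 0.15, adjusted p = 0.000757, and adjusted p = 0.772 with an estimated correlation), with the hexokinase Hk2 at 0.67 ± 0.39, Pdk1 at 0.42 ± 0.25, Slc2a1 as above and Ankrd37 at 0.26 ± 0.20. This rested on KO replicate 2, whose list median was 0.52 against -0.05 and -0.01 in the other KO libraries and where Pdk1 was at 3495; without it the list median was -0.04.

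Among the lower lists, 32 of 33 oxidative phosphorylation genes were lower in KO (median log2 -0.07, adjusted p = 5.19e-07, and adjusted p = 0.749 with an estimated correlation). They included the ATP synthase subunit Atp5o (-0.10 ± 0.05), Ndufv1 of complex I (-0.10 ± 0.05), and Uqcrc1 (-0.09 ± 0.05) and Uqcrfs1 (-0.11 ± 0.06) of complex III. 41 of 43 cytosolic ribosomal protein genes were lower (median -0.06, adjusted p = 1.50e-06, and adjusted p = 0.749 with an estimated correlation), with Rps16 at -0.14 ± 0.05, Rps27 at -0.81 ± 0.45, Rps2 at -0.09 ± 0.05 and Rpl18 at -0.10 ± 0.06. Rps27 was near the filter on low values, at 26.9 ± 2.14 in WT. Ribosomal protein genes have many processed pseudogenes, so their values are uncertain where reads could be split. Of the genes near Cyfip2 on chromosome 11, 14 of 21 were lower (median -0.07, adjusted p = 0.000567, and adjusted p = 0.175 with an estimated correlation), with Fndc9 the 1 member that passed adjusted over the list alone (adjusted p = 0.00082). Without Fndc9 the list's adjusted p was 0.00925. Its other members included the Mediator subunit Med7 (-0.26 ± 0.08), the tRNA-modifying enzyme Thg1l (-0.20 ± 0.09) and Havcr2 (-0.72 ± 0.34).

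**Figure D3:**
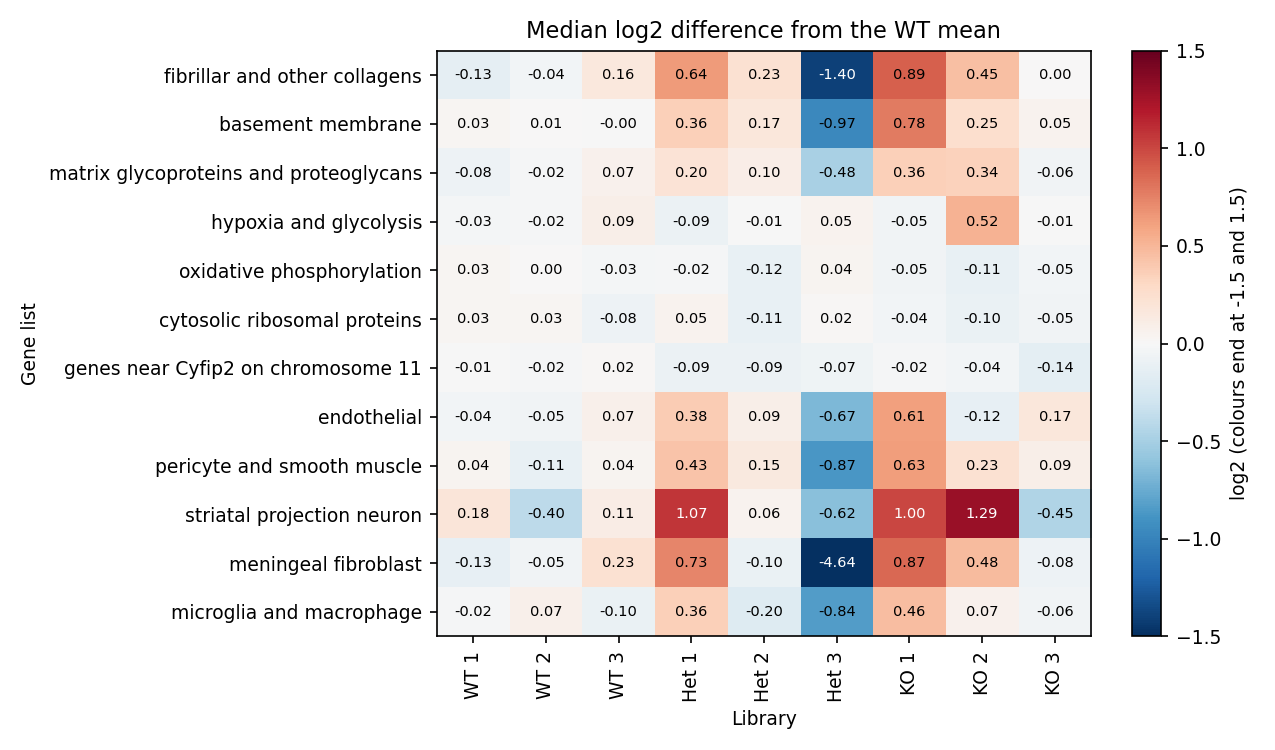
Median log2 difference from the WT mean of each gene list (rows) in each of the 9 libraries (columns), for the 10 lists called between KO and WT and for the meningeal and the microglia and macrophage lists. The meningeal median is -4.64 in Het replicate 3, and the striatal median is 1.00 or above in Het replicate 1, KO replicate 1 and KO replicate 2.

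The other 25 lists were not called between KO and WT. Among them, all 23 meningeal fibroblast markers (median 0.37) and 16 of 18 microglia and macrophage markers (median 0.12) had positive values, the same direction as the matrix and vascular lists. The adjusted p was 0.0526 for growth hormone and IGF signalling, 0.0819 for meningeal fibroblasts, 0.085 for intermediate progenitors, 0.104 for microglia and macrophages, 0.136 for the synapse and for interneurons, and 0.141 for p53 and apoptosis and for muscle and skin. It was 0.152 for the oligodendrocyte lineage, matrix crosslinking and other brain regions, 0.211 for actin regulators and deep layer neurons, 0.298 for radial glia and astrocytes, 0.426 for immediate early genes, 0.472 for upper layer neurons, and 0.534 for erythroid genes and the cell cycle. It was 0.642 for FMRP and translation partners, 0.672 for choroid plexus, 0.75 for the unfolded protein response, axon guidance and the WAVE complex, 0.84 for hippocampus and 0.927 for Cajal-Retzius cells. The median and the test differed in sign for 3 of these, the erythroid, unfolded protein and WAVE lists.

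The comparison of Het with WT asked what the loss of 1 copy of Cyfip2 does. Cyfip2 stood at 90.4% of its WT level, a log2 fold change of -0.15 ± 0.06, and Fndc9 at -0.93 ± 0.48. Meningeal fibroblast genes were lower in Het for all 23 members, with a median log2 of -1.19, and this rested on Het replicate 3. Alpha-globin Hba-a1 was at 10824 ± 1648 in WT and 16720 ± 1058 in Het (SD, n = 3).

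limma called 0 genes over all genes tested, with a smallest adjusted p of 1.00, and 242 genes had an unadjusted p under 0.05, 145 higher and 97 lower, where 753 would be expected by chance. The groups did not overlap for 6.67% of genes, where chance gives 10%. Those with the smallest p, none passing, were Ciz1, which acts in DNA replication, at 4026 ± 141 in WT and 4729 ± 58.5 in Het (log2 0.23 ± 0.05), the RNA-binding protein Igf2bp1 (0.23 ± 0.06), Rint1 (0.49 ± 0.12), Mrps23 (-0.41 ± 0.10), the ESCRT subunit Vps25 (-0.25 ± 0.07) and the mitochondrial transcription factor Tfam (-0.51 ± 0.14).

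5 of 35 lists were called with the preset correlation and 0 with an estimated correlation or with fry; no member of any list passed, over all genes or adjusted over the list alone. For the meningeal list the adjusted p was 2.55e-05, and adjusted p = 0.843 with an estimated correlation. Its members Mgp, Slc13a4, Foxc2 and Slc6a13 had log2 fold changes of -1.17 ± 0.75, -1.57 ± 1.07, -1.71 ± 1.20 and -1.86 ± 1.45. Without Het replicate 3 the list was called in the opposite direction, with a median of 0.25. Of the microglia and macrophage genes, 16 of 18 were lower (median -0.26, adjusted p = 0.00524, and adjusted p = 0.843 with an estimated correlation), with the microglial receptor Trem2 at -0.39 ± 0.20, Aif1 at -0.44 ± 0.27, Cd163 at -1.45 ± 1.14 and Pf4 at -1.12 ± 0.90; without Het replicate 3 the median was 0.16.

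All 7 erythroid genes were higher in Het (median 0.53, adjusted p = 0.00524, and adjusted p = 0.843 with an estimated correlation), with Hba-a1 at 0.64 ± 0.38, the heme synthesis gene Alas2 at 0.63 ± 0.39, Hba-a2 at 0.49 ± 0.42 and Hbb-bs at 0.44 ± 0.42. Hba-a1 and Hba-a2 are near-identical copies, so the split of reads between them is uncertain. The erythroid median relative to WT was 0.46 in WT replicate 1, above the 0.28 of Het replicate 3. Oxidative phosphorylation genes were lower for 23 of 33 members (median -0.03, adjusted p = 0.0332, and adjusted p = 0.843 with an estimated correlation), with Cox7c at -0.26 ± 0.10, Ndufb5 at -0.19 ± 0.08 and Sdhd at -0.09 ± 0.05; without Het replicate 2, a library with choroid plexus RNA, the list was not called and pointed the other way. Genes near Cyfip2 were lower for 18 of 21 members (median -0.05, adjusted p = 0.0332, and adjusted p = 0.745 with an estimated correlation), with Ttc1 at -0.14 ± 0.08, Lsm11 at -0.17 ± 0.12 and Slu7, against the list's direction, at 0.18 ± 0.12. Without Fndc9 that list was not called (adjusted p = 0.0757).

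The comparison of KO with Het tested the difference between the mutant genotypes. Cyfip2 was lower in KO by a log2 fold change of -0.27 ± 0.06 and passed adjusted over the WAVE list alone (adjusted p = 0.0191) but not over all genes (adjusted p = 0.942). Fndc9 had a log2 fold change of -2.71 ± 0.48 and passed adjusted over the list of genes near Cyfip2 alone (adjusted p = 0.00721). Meningeal fibroblast genes were higher in KO for all 23 members, by a median log2 of 1.67, with the matrix protein Mgp at 79.3 ± 62.0 in Het and 151 ± 10.8 in KO (log2 1.49 ± 0.75). Microglia and macrophage genes were higher for all 18 members, with Pf4 at 1.53 ± 0.90. Both lists had an adjusted p = 0.627 with an estimated correlation and rested on Het replicate 3, where their medians relative to WT were -4.64 and -0.84.

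limma called 0 genes, with a smallest adjusted p of 0.942; 541 genes had an unadjusted p under 0.05, 214 higher and 327 lower, where 753 would be expected by chance. The groups did not overlap for 7.82% of genes, where chance gives 10%. The smallest p, none passing over all genes, belonged to Aloxe3 (1.24 ± 0.22), the transcription factor E2f3 (0.50 ± 0.10) and the Wnt regulator Dact1 (0.35 ± 0.07) among the higher genes, and to Fndc9, Ciz1 (-0.24 ± 0.05) and Ly6g6e (-0.70 ± 0.14) among the lower ones.

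16 of 35 lists were called with the preset correlation, 10 higher and 6 lower in KO, and 0 with an estimated correlation or with fry. The meningeal list had an adjusted p of 3.01e-07 and the microglia and macrophage list 6.16e-05, and with an estimated correlation adjusted p = 0.627 for each. The lists also called higher were basement membrane (19 of 21, median 0.53), collagens (22 of 24, 0.59), pericyte and smooth muscle (15 of 15, 0.45), endothelial (16 of 18, 0.39), matrix glycoproteins (28 of 35, 0.25), matrix crosslinking (20 of 26, 0.18) and hypoxia and glycolysis (18 of 21, 0.21), and for each of them adjusted p = 0.627 with an estimated correlation. Without KO replicate 2 the hypoxia median was 0.019 and the list was not called. The interneuron list was called higher for 16 of 19 members (median 0.20, adjusted p = 0.0282, and adjusted p = 0.649 with an estimated correlation), but its medians relative to WT were high in the 4 libraries with olfactory bulb RNA (0.23 to 0.48) and -0.53 in KO replicate 3, below all 3 Het libraries. The members of these lists with the smallest p were Lamc1 (0.59 ± 0.22), Col5a3 (0.65 ± 0.30), Higd1b (0.41 ± 0.21), Robo4 (0.46 ± 0.23), the elastin gene Eln (0.35 ± 0.18), Timp3 (0.56 ± 0.21), the glucose transporter Slc2a3 (0.33 ± 0.17) and the transcription factor Maf (0.24 ± 0.08).

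The lists called lower in KO than Het were cytosolic ribosomal proteins (33 of 43, median -0.04), cell cycle (25 of 30, -0.15) and intermediate progenitors (10 of 12, -0.20), for each of which adjusted p = 0.663 with an estimated correlation. Without KO replicate 3 the cell cycle median was 0.066 and that of intermediate progenitors -0.0078, and the ribosomal median was 0.00043 with quantile rescaling and 0.0040 with array weights. Deep layer neurons (11 of 15, -0.12) and FMRP and translation partners (7 of 10, -0.07) were also called lower, with adjusted p = 0.627 with an estimated correlation for each. Erythroid genes (5 of 7, -0.57) were called lower too, with adjusted p = 0.649 with an estimated correlation. Their median relative to WT was 1.05 in KO replicate 1, above all 3 Het libraries. It was -0.82 and -0.40 in KO replicates 2 and 3. With the replicate number as a block the FMRP and translation partners were not called (adjusted p = 0.0829), and the synapse list was called higher (adjusted p = 0.0206 with the block, 0.065 without it, and adjusted p = 0.663 with an estimated correlation without it). Members with the smallest p were Rpl18 (-0.10 ± 0.06), the replication clamp Pcna (-0.22 ± 0.09), the somatostatin receptor Sstr2 (-0.37 ± 0.13), Nxph3 (-0.33 ± 0.12), the translation repressor Eif4ebp2 (-0.14 ± 0.05) and Hba-a1 (-0.70 ± 0.38). Without Het replicate 3, 5 lists were called in place of 16, and the meningeal, vascular and matrix lists were not among them.

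The comparison of Het with the midpoint of WT and KO tested whether Het lay between the other genotypes. Ciz1 stood above the midpoint in Het by a log2 difference of 0.24 ± 0.04 and E2f3 below it by -0.42 ± 0.09, and neither passed. Meningeal fibroblast genes lay below the midpoint for all 23 members (median -1.47, and 0.11 without Het replicate 3), with Mgp at -1.33 ± 0.65, and erythroid genes above it for all 7 (median 0.51), with Hba-a1 at 0.67 ± 0.33.

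limma called 0 genes, with a smallest adjusted p of 0.992, and 434 genes had an unadjusted p under 0.05, where 753 would be expected by chance. Besides Ciz1 and E2f3, the smallest p belonged to the RNA-binding protein Rbm38 (0.42 ± 0.09), the ubiquitin ligase Rnf123 (0.25 ± 0.05), the protocadherin Pcdhgc4 (-0.38 ± 0.08) and Eid1 (-0.17 ± 0.04). 15 of 35 lists were called with the preset correlation, 5 above and 10 below the midpoint, and 0 with an estimated correlation or with fry. The meningeal list had an adjusted p of 1.15e-07, and adjusted p = 0.757 with an estimated correlation. The other lists below were microglia and macrophages, with Trem2 at -0.34 ± 0.17, collagens, with Col5a3 at -0.49 ± 0.26, basement membrane, with Lamc1 at -0.29 ± 0.19, pericyte and smooth muscle, with Tagln at -1.02 ± 0.69, and endothelial, with Robo4 at -0.28 ± 0.20. They also included matrix glycoproteins, with Mfap5 at -0.69 ± 0.41, matrix crosslinking, with Timp3 at -0.37 ± 0.19, hypoxia and glycolysis, with Slc2a3 at -0.27 ± 0.15, and the unfolded protein response, with Xbp1 at -0.15 ± 0.07. For each of these lists adjusted p = 0.757 with an estimated correlation. The lists above were the erythroid list, deep layer neurons, with Sox5 at 0.24 ± 0.09, FMRP and translation partners, with Eif4ebp2 at 0.11 ± 0.04, and axon guidance, with the adhesion protein Cntn2 at 0.23 ± 0.07, for each of which adjusted p = 0.757 with an estimated correlation, and the cell cycle, with Pcna at 0.17 ± 0.08 and adjusted p = 0.849 with an estimated correlation. Without Het replicate 1 the cell cycle median was -0.021. The axon guidance list had a mean log2 difference of -0.03 against a median of 0.06. Without Het replicate 3, 8 lists were called, and the medians of 7 lists named above as below the midpoint were positive: meningeal (0.11), collagens (0.23), basement membrane (0.13), matrix glycoproteins (0.067), matrix crosslinking (0.065), endothelial (0.10) and pericyte and smooth muscle (0.097).

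The log2 fold changes of Het against WT and of KO against WT share their WT libraries and so covary by chance. Across genes, which are not independent replicates, their covariance was 0.0135 (r = 0.187). Unchanged groups simulated against shared WT libraries gave 0.0590 (r = 0.50), so the difference was -0.0455. The simulation gave all libraries the pooled spread of each gene. The WT libraries spread less, with root mean square residuals of 0.24 to 0.30 against 0.29 to 0.49 in the others. The simulated value is thus too high, and the difference cannot be read as opposed Het and KO effects. Of 100 random regroupings of the 9 libraries, 94 gave a covariance as large, with a range from -0.0048 to 0.146.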

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

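The tests with sex, the olfactory bulb score or the meningeal score as a covariate, with array weights, and without Het replicate 3 and KO replicate 3 together were chosen after seeing the data, as were the fit to the Het and KO libraries alone with the replicate block and the use of an estimated correlation and fry beside a covariate. The other alternatives were fixed before the data were examined.

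Cyfip2 stayed lower in KO than WT under all alternatives run, with a log2 fold change from -0.34 (sex as a covariate) to -0.45, with adjusted p from 0.114 (array weights) to 1, and passed over all genes under none. Fndc9 stayed lower too, from -2.60 with a pseudocount of 5 to -4.00 without KO replicate 2, with adjusted p from 0.050 (quantile rescaling) to 1; the filters at a mean of 50 and at 1 per M (mega) leave it out. Of the 242 gene results that the rule for named genes takes, 51 changed direction under at least 1 alternative and 2 passed the threshold under 1, Ciz1 and Pcdhgc4 against the midpoint with array weights. Of the 120 gene results in the text, 18 changed direction under at least 1 alternative. No cause was tested for the changes below, except where fewer libraries or a covariate made the alternative.

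Camera with an estimated correlation, fry, and fry with the replicate block each called 0 lists in all 4 comparisons. With the replicate block, limma called 0 genes in each comparison and camera 12 lists for KO against WT, 7 for Het against WT, 16 for KO against Het and 13 for the midpoint. A fit to the Het and KO libraries alone with the replicate block called 0 genes and 16 lists for KO against Het. Besides the FMRP and synapse lists, neither fit with the block changed the call of a list between KO and Het. Without a filter on low values, 3 lists were called for Het against WT. With the groups compared alone, 1 gene was called for Het against WT and 1 for KO against Het. With quantile rescaling the ribosomal list median for KO against Het was 0.00043 and with array weights 0.0040, both in the reverse direction and not called.

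Sex as a covariate turned the medians of 6 lists between KO and WT: collagens (-0.34), basement membrane (-0.095), matrix glycoproteins (-0.10), pericyte and smooth muscle (-0.076), striatal neurons (-0.39) and endothelial (-0.0042), the last with camera's direction still higher. It also reversed Col25a1 (-0.34), Col11a1 (-0.088), Lama4 (-0.092), Adora2a (-0.11), Wasf1 (0.12), Nckap1l (-0.21), Nckap1 (0.042), Wasf2 (-0.22), Wasf3 (0.037) and Brk1 (-0.044). With it 16 lists were called for Het against WT. Because all WT libraries are male, this covariate is estimated from the Het and KO libraries alone.

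With the meningeal score as a covariate, 16 lists were called for KO against WT, 13 for Het against WT, 5 for KO against Het and 7 for the midpoint. Wasf2 was at -0.016 between KO and WT. Between Het and WT the meningeal list was at 0.068 and the microglia and macrophage list at 0.023. Between KO and Het the collagens were at -0.061 and the endothelial list at -0.0026. Against the midpoint the collagens were at 0.18, basement membrane at 0.087, matrix glycoproteins at 0.054, matrix crosslinking at 0.043, the meningeal list at 0.053, the endothelial list at 0.090 and pericytes at 0.082. The score shares genes with the meningeal list. With the olfactory bulb score as a covariate, 3 lists were called for Het against WT and Wasf1 was at 0.020 between KO and WT, where the collagens and the matrix glycoproteins were no longer called.

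With array weights, 1 gene was called for Het against WT and 2 against the midpoint, and 9 lists were called for KO against Het. Brk1 was at -0.019 between KO and WT and Mgp at 0.034 between Het and WT.

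Without Het replicate 3 and KO replicate 3 together, 1 gene and 21 lists were called for KO against WT, 1 gene and 14 lists for Het against WT, and 6 lists for the midpoint. Abi2 was at -0.0021 between KO and WT. Between Het and WT the meningeal list was at 0.25, the microglia and macrophage list at 0.16, Slc6a13 at 0.23, Cd163 at 0.15 and Pf4 at 0.14. Against the midpoint the collagens were at 0.10, basement membrane at 0.072, matrix glycoproteins at 0.024, the endothelial list at 0.10, pericytes at 0.053 and Tagln at 0.057.

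Leaving out 1 library at a time gave 0 to 1 genes in each of the 4 comparisons. The genes called in this way were Lenep without WT replicate 1 and the gene models Gm14288 without Het replicate 1 and Gm3650 without KO replicate 3, named here after their values were seen. For KO against WT it gave 7 lists (without WT replicate 1) to 19 (without KO replicate 3). The hypoxia list ran from -0.039 (without KO replicate 2) to 0.28, Wasf1 from -0.070 to 0.040, Abi2 from -0.0021 to 0.16, Wasf2 from -0.14 to 0.18, Wasf3 from -0.13 to 0.00032, Cyfip1 from -0.011 to 0.051 and Brk1 from -0.0061 to 0.045. For Het against WT it gave 4 lists (without WT replicate 1) to 14 (without Het replicate 3). Oxidative phosphorylation ran from -0.058 to 0.0045 (without Het replicate 2), the meningeal list from -2.19 to 0.25, the microglia and macrophage list from -0.55 to 0.16, Slc6a13 from -3.16 to 0.23, Cd163 from -2.50 to 0.15 and Pf4 from -1.99 to 0.14, each of the last 5 with its high end without Het replicate 3.

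For KO against Het it gave 5 lists (without Het replicate 3) to 20 (without KO replicate 3). The collagens ran from -0.033 (without Het replicate 3) to 0.94, the cell cycle from -0.35 to 0.066 (without KO replicate 3), hypoxia from 0.019 (without KO replicate 2) to 0.32 and intermediate progenitors from -0.37 to -0.0078 (without KO replicate 3). For the midpoint it gave 8 lists (without Het replicate 3) to 17. The collagens ran from -0.77 to 0.23, basement membrane from -0.61 to 0.13, matrix glycoproteins from -0.34 to 0.067, matrix crosslinking from -0.22 to 0.065, the meningeal list from -2.47 to 0.11, the endothelial list from -0.45 to 0.10, pericytes from -0.53 to 0.097, Robo4 from -0.47 to 0.0064 and Tagln from -1.84 to 0.017, each with its high end without Het replicate 3. The cell cycle ran from -0.021 (without Het replicate 1) to 0.30. The covariance of the Het and KO log2 fold changes ran from -0.0079 (without Het replicate 1) to 0.0427 (without WT replicate 3).

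edgeR, DESeq2, limma-voom and their size factors were not run, because the values are not counts. The midpoint has no fit to the compared groups alone. Depth limits the low genes, where 1 read is worth 0.675 to 1.22 units.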

Other observations

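The tests of wild-type RNA mixed into the KO libraries, of a KO library with a wrong label and of chromosome 11 among the smallest p-values were chosen only after the result was seen, as were the covariates and the estimated correlation and fry beside them.

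5 matrix and vascular lists were called higher in KO than WT with the preset correlation, and 0 with an estimated correlation (adjusted p from 0.772 to 0.792) or fry (adjusted p = 0.928). The KO libraries did not act alike: 2 of 3 lay above all WT libraries, and without KO replicate 1 0 of 5 lists were called. With the meningeal score as a covariate 5 of 5 were called with the preset correlation. Their medians were 0.10 to 0.27 in place of 0.22 to 0.42. A rule set beforehand took most of these lists keeping their call as going against unequal meningeal tissue as their source. Median member SEs also fell, to 0.14 to 0.21 with the score from 0.30 to 0.53 without it. Calls could thus be kept at smaller fold changes, so the kept calls cannot decide this question. The medians shrank, and all 23 meningeal fibroblast markers were also higher in KO than WT, so a part for such tissue is not excluded. An estimated correlation (smallest adjusted p 0.162) and fry (smallest adjusted p 0.338) called 0 with the score. They also called 0 without it, so they do not bear on this. With sex as a covariate 0 of 5 were called, with medians from -0.34 to -0.0042. Median member SEs were 0.32 to 0.50 (0.30 to 0.53 without it), so the call ended because the fold changes went to or below 0. All WT libraries are male, so this covariate was estimated from the Het and KO libraries alone. These include the male Het replicate 3, at -0.76 over the matrix and vascular genes. The fit thus cannot separate sex from the state of that library. More female embryos among the KO libraries may be the source, but the 3 female libraries also carried olfactory bulb RNA. With the olfactory bulb score as a covariate 3 of 5 were called, and the medians of all 5 were 0.061 to 0.20. With that score an estimated correlation called 0 (smallest adjusted p 0.935). A genotype effect of unequal size stays open.

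The meningeal and the macrophage list were called lower in Het than WT with the preset correlation, but not with an estimated correlation (adjusted p = 0.843 for both) or fry (0.858). Without Het replicate 3, 0 of 2 lists were still called lower, so Het replicate 3 alone, with less meningeal tissue, is a candidate explanation. By their medians 2 of 3 Het libraries lay below all WT libraries, at -0.12 in Het replicate 2 and -2.85 in Het replicate 3, against -0.11 in the lowest WT library and 0.58 in Het replicate 1. The Het libraries thus did not act alike.

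Cyfip2 RNA was still present in the KO libraries at 74.7% of WT. Reads of the paralog Cyfip1 do not explain it, since 0% of 31-base words in Cyfip2 transcripts occur in Cyfip1 transcripts. Wild-type RNA mixed in would hold up Fndc9 as well, but the upper 95% limit of its log2 fold change was -2.55 against a lower limit of -0.56 for Cyfip2. A wrong label is argued against by 3 of 3 KO libraries with Cyfip2 below every WT and Het library. A mutant allele that leaves most of the RNA in place may account for it, and the labels do not describe the allele.

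The 62 other genes within 5 Mb of Cyfip2 had a median log2 fold change of -0.013 between KO and WT, at percentile 31.7 of 13679 windows. Between Het and WT the median of these genes was further below 0, at -0.041, and no percentile is given for it. Chromosome 11 held 14 of the 100 genes with the smallest p where 7.95 were expected, an odds ratio of 1.89 (95% interval 0.99 to 3.37, Fisher exact p = 0.0381). Cyfip2 itself, Fndc9 within it, Mrps23 and Aloxe3, all named above for a small p, lie on this chromosome.

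Splits of the libraries were counted, the real one included in each count below. Where the real count of genes is 0 all splits give as many, so those gene counts say nothing about chance. For pairs of groups there are 10 splits, too few for a share under 0.05. For KO against WT, 10 of 10 splits gave as many genes (real 0, highest other 1) and 7 of 10 as many lists (real 10, highest other 18). For Het against WT, 10 of 10 gave as many genes (real 0, highest other 1) and 10 of 10 as many lists (real 5, highest other 18). For KO against Het, 10 of 10 gave as many genes (real 0, highest other 12) and 5 of 10 as many lists (real 16, highest other 22). For the midpoint, 100 of 100 regroupings gave as many genes (real 0, highest other 1421) and 48 of 100 as many lists (real 15, highest other 23). By the lists chance is not excluded. A random regrouping of the libraries gave the 1421 genes, and what sets its libraries apart was not tested. Beside these counts of 0 genes by limma, 178, 242, 541 and 434 genes had an unadjusted p under 0.05. By chance 753 would be expected in each comparison, but a single grouping can lie far from that. The splits ran from 123 to 1357 such genes for KO against WT, 99 to 1215 for Het against WT and 116 to 3529 for KO against Het. Counts below 753 thus do not show that genotype has no effect.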
